A study of Arabidopsis thaliana with 7 samples.

How the data were processed

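Small RNA libraries from immature flower buds (inflorescence stages 1 to 12) of Arabidopsis thaliana, ecotype Columbia, were deposited for wild type (3 libraries) and for aly1-2, pol IV, pol V and dcl2 (1 library each). Per the labels, small RNA was isolated with Trizol and mirVana, made into libraries with a TruSeq small RNA kit and sequenced on a HiSeq2500 instrument. The deposited files hold RPM values, which the authors scaled to the sum of each library's own deposited sequences of 18 to 28 nt, with a line per distinct sequence. This was read from the values: each file summed to 1000000 and 100% of its values were whole multiples of the smallest one, within a relative tolerance of 1e-05, so whole reads could be recovered. The genome build named by the authors is TAIR10, and the aligner, trimming and filters are not given in the sources used here. Each file is labelled as a single library, and columns were not pooled here. The series text speaks of 3 replicates of wild type and 4 mutants, which can be read with or without replicates of the mutants; the samples hold 1 library per mutant.

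Sequences were matched without mismatch to the TAIR10.1 reference on both strands with code written for this purpose. All 4629468 distinct sequences matched at least once (100%); the authors' filters are not given, so this share may only reflect that the tables hold matched sequences. A sequence with several matches was divided equally among them. 24-nt values were summed in windows of 1000 bp, and 21-nt and 22-nt values over annotated genes on both strands, so that genes overlapping each other share reads. miRNAs and tasiRNAs were taken as exact mature sequences from a list of 54 fixed in advance, of which 52 were detected. Lists of silencing, development, auxin, nutrient, pollen, phasing trigger and tasiRNA members, and of TAS genes, phased transcripts and silencing factors, were fixed in advance too. Pericentromeres were set at 11 to 18 Mb on chromosome 1, 1 to 7 Mb on 2, 10 to 17 Mb on 3, 1 to 6 Mb on 4 and 9 to 16 Mb on 5. The annotation has no transposable element features, and transposon genes fall in its pseudogene class.

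Each mutant was compared with wild type, and aly1-2 with each other mutant for 24-nt windows. limma (lmFit and eBayes, with trend and robust off) was fitted to log2(RPM + 1) with a coefficient per genotype. Windows and genes needed a mean of at least 2 RPM and miRNAs of at least 5 RPM over the libraries. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 within the contrast and an absolute log2 fold change of at least 1. The residual degrees of freedom were 2, all from wild type, and 9.67, 7.84 and 8.89 in total for miRNAs, genes and windows after moderation. A single mutant library is thereby assumed to vary like wild type. The labels do not say whether the wild-type libraries came from separate plants, so p-values measure the spread between these libraries, which may be technical. Length classes, chromosome regions and annotation classes were given no test beyond an exact permutation, whose smallest p is 0.25; a fit that pools the spread was not run on them. Intervals of shares are Wilson intervals and those of the mutated genes exact Poisson intervals, both at 95%, and they hold counting error alone. Windows dependent on Pol IV were those called lower in pol IV with a log2 fold change of at most -2. Values expected from the shared wild-type libraries were taken from 20 simulations of unchanged mutant libraries. These comparisons, thresholds, lists and alternatives were set before the data were examined.

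Named features followed a rule set at the same time. For windows and genes these were the 5 largest rises and 5 largest falls among those called, with all members of the gene lists. For miRNAs they were up to 20 per comparison, filled by absolute log2 fold change from those outside the wild-type range where few were called, with the silencing and tasiRNA lists. Other members named by value in the text, and the miR398b,c spread, were picked after their values were seen.

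The alternatives were a pseudocount of 0.25, no filter on low values, scaling to equal sums of the listed miRNAs, TMM scaling over the tested features, and edgeR's quasi-likelihood test and DESeq2 on recovered reads, where a missing DESeq2 p-value stayed missing and the window or gene was not counted as tested. Further ones were each wild-type library left out, sequences with 1 genome match, windows of 500 bp, and 21 nt or 22 nt alone. Others were miRNA variants within 2 nt of the mature ends, other thresholds for dependence on Pol IV, and removal of matches to annotated tRNA or rRNA genes or the organelles. The edgeR fit was also scaled by TMM, and the DESeq2 fit by its own size factors over the tested features, so both differ from the main fit in scaling too. Thinning every library to 2367811 reads and testing every annotated mature miRNA were added after seeing the data. The test was tried on simulated data with 200 changed windows or genes in a mutant library. At log2 fold changes of -4, -2, 2 and 4 it recovered 68, 8, 28 and 100% of windows and 58, 18, 22 and 98% of genes, and called 3 of 23043 unchanged windows and 2 of 2481 unchanged genes. It recovered 0 of 12 changed miRNAs.

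Recovered reads numbered 2367811 to 7921141 per library. The 10 most abundant sequences took 65.6% of reads in pol IV, 27.0% in pol V and 9.13 to 23.8% in wild type. Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and data.table (1.17.8), and Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.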

Results

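Small RNAs of 18 to 28 nt were sequenced from immature flower buds of Arabidopsis thaliana, ecotype Columbia, in 7 libraries. Wild type had 3 libraries, and aly1-2, pol IV, pol V and dcl2 had 1 library each. ALY1 belongs to a family of nuclear adaptor proteins that hand mRNA to the export machinery. Pol IV and Pol V are plant RNA polymerases of RNA-directed DNA methylation: Pol IV makes the precursors of 24-nt siRNAs, and Pol V makes the scaffold transcripts to which those siRNAs guide methylation. DCL2 is the Dicer-like enzyme that makes 22-nt siRNAs. The series presents the other mutants as controls for aly1-2. The question was therefore which small RNAs differed in aly1-2 and how that set compared with loss of the siRNA pathway. The labels give the genotype alone and name no subunit or allele for pol IV and pol V. Values were deposited as RPM, reads per 1000000 reads of the library, for each distinct sequence. The recovered read numbers were 3102622, 3643541 and 2367811 for wild type 1, 2 and 3, 7921141 for aly1-2, 2528238 for pol IV, 7092048 for pol V and 2649818 for dcl2. A single read was therefore worth between 0.126 RPM in aly1-2 and 0.422 RPM in wild type 3. Errors of wild-type values are SDs with n = 3, and mutant values have no replicate; the series text can also be read as giving the 4 mutants 3 replicates each, which the deposited samples do not show.

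Small RNAs matching the mutated genes were examined first, although they carry no information on mRNA level and so do not check the genotype labels. ALY1 (AT5G59950, chromosome 5, 24139939 to 24141937) gave 0.379 RPM of 21-nt and 22-nt small RNAs in aly1-2 and 0 to 0.645 RPM in wild type. DCL2 (AT3G03300, chromosome 3, 767880 to 776214) gave 0 RPM in dcl2, where the upper 95% limit of the count was 1.39 RPM, and 0.274 to 0.645 RPM in wild type; at 18 to 28 nt it gave 4.91 RPM, from 13 reads, within the wild-type range of 0.549 to 5.16 RPM. NRPD1 (AT1G63020, chromosome 1, 23354685 to 23362589), the largest subunit of Pol IV, gave 1.98 RPM in pol IV, from 5 reads, against 0 to 0.422 RPM in wild type, and was also above wild type in aly1-2 (1.39 RPM, 11 reads) and pol V (0.705 RPM, 5 reads). NRPE1 (AT2G40030, chromosome 2, 16714460 to 16723718), the largest subunit of Pol V, gave 6.63 RPM in pol V (exact Poisson 95% interval 4.87 to 8.81) and at most 0.274 RPM in wild type.

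The 24-nt class, which holds the products of the Pol IV pathway, made up 3.56% of the pol IV library (Wilson 95% interval 3.53 to 3.58) against 51.2% ± 6.76 in wild type. It was within the wild-type range in aly1-2 (55.9%) and pol V (48.1%), and above all 3 wild-type libraries in dcl2 (60.7%, interval 60.6 to 60.7). The 21-nt class, which holds most miRNAs, was 68.6% in pol IV, 30.4% in pol V, 16.3% in aly1-2 and 17.04% in dcl2, against 20.7% ± 6.70 in wild type. The 22-nt class was 3.55% in dcl2 (interval 3.53 to 3.58) and 7.89% in aly1-2, against 6.97% ± 0.664 in wild type with a range of 6.20 to 7.39%. The 23-nt class was below all 3 wild-type libraries in pol IV (2.32%) and pol V (6.25%), against 9.53% ± 1.42. An exact permutation test of 1 library against 3 has 4 arrangements and a smallest p of 0.25. No length class could reach 0.05 in that test, the only one used for these shares, and chance places a mutant above all 3 wild-type libraries 25% of the time. When libraries were scaled to equal sums of listed miRNAs, the log2 ratio of the 21-nt class to wild type turned from 1.73 to -0.33 in pol IV and from 0.55 to -0.22 in pol V. Listed miRNAs, mostly of 21 nt, summed to 651817 RPM in pol IV and 266654 RPM in pol V. This scaling therefore largely fixes the 21-nt class in advance. Its factors were 1.35, 1.02 and 2.74 in wild type 1, 2 and 3. Reads in genes annotated as tRNA or rRNA, or in the organelles, are a partial sign of RNA quality. They were 2.67% in pol IV, 0.814% in pol V, 1.55% in aly1-2 and 1.43% in dcl2, and 1.78%, 1.31% and 1.16% in wild type. Only 11 genes are annotated as rRNA, so any rRNA reads outside them are left out.

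**Figure D1:**
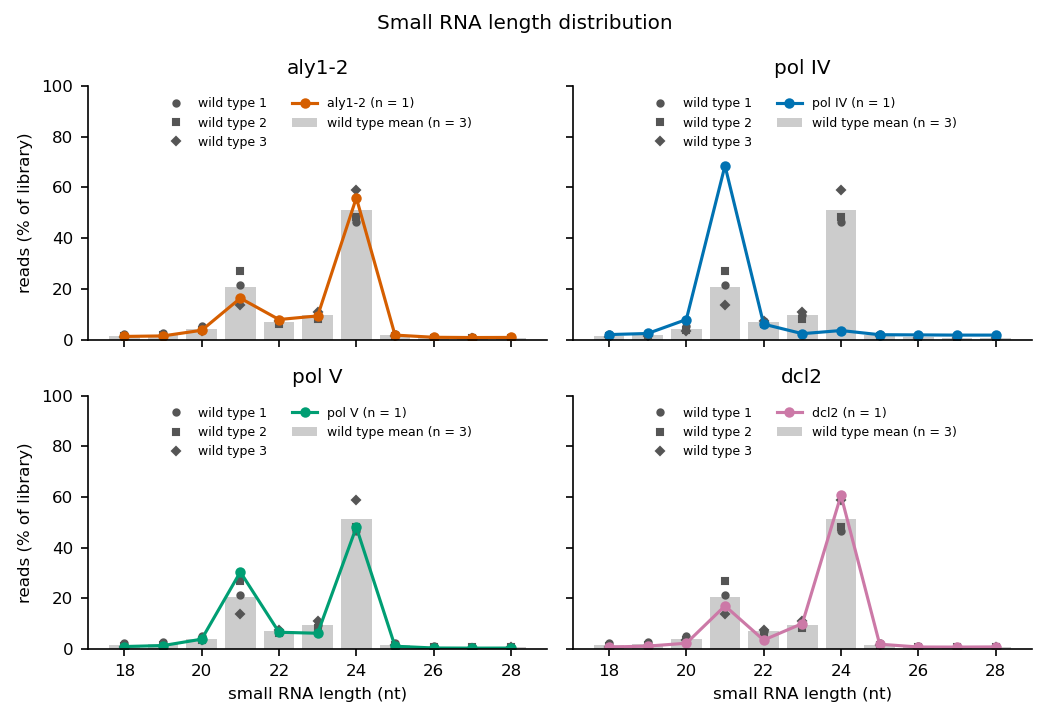
Share of each library's reads (y axis, %) by small RNA length (x axis, nt), with 1 panel per mutant. Grey bars are the wild-type mean (n = 3), grey symbols the 3 wild-type libraries and the coloured line the single mutant library; the 24-nt peak is at 3.56% in pol IV and the 22-nt class at 3.55% in dcl2.

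Loss of Pol IV took away 24-nt small RNAs from nearly every measured part of the genome. Of 23243 windows of 1 kb tested, 22744 fell and 99 rose in pol IV, with a median log2 fold change of -2.70 over all windows. The window at 2560001 to 2561000 on chromosome 4, between genes and 2040 bp from VPS28-2, fell from 1574 ± 503 RPM to 2.90 RPM, and the window at 8039001 to 8040000 on chromosome 2, which overlaps the protein-coding gene AT2G18530, fell from 784 ± 129.9 RPM to 1.19 RPM. The window at 13675001 to 13676000 on chromosome 1, 796 bp from AT1G36320, was at 339.7 ± 178 RPM in wild type and at 0 in pol IV. Among the 99 windows that rose, 32 overlapped a miRNA gene, 23 a tRNA, rRNA, snRNA or snoRNA gene and 54 a protein-coding gene. MIR319a (chromosome 4, 12353001 to 12354000) gave the largest rise, from 3.52 ± 3.13 to 134 RPM (log2 fold change 5.12, SE 0.64, limma adjusted p = 7.54e-05), and windows at MIR319b and MIR160c also rose. Windows over the non-coding gene AT4G26255 reached 265 RPM against 9.07 ± 4.56. Under scaling to equal miRNA sums 5 windows rose and 20721 fell (median -3.34), and under TMM 1356 rose and 17190 fell (median -1.65). edgeR called 266 windows, of which 264 were higher, and DESeq2, which gave an adjusted p to 2514 windows, called 645, of which 200 were higher, while the median log2 fold change in edgeR was -7.18. The edgeR fit was itself scaled by TMM, with a factor of 0.0451 in pol IV and 1.39 to 2.19 in the other libraries. DESeq2 used its own size factors. The calls of edgeR and DESeq2 are therefore no check on direction apart from scaling.

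In aly1-2, 24-nt windows called lower lay more often in chromosome arms and over protein-coding genes. Those called higher lay more often in pericentromeres and over pseudogenes, the class that holds the annotated transposon genes. Of the 23243 windows, 3518 fell and 2173 rose. The window at 10654001 to 10655000 on chromosome 3, in the protein-coding gene AT3G28420, fell from 168 ± 26.2 to 0.252 RPM (log2 fold change -7.07, SE 0.39, limma adjusted p = 0.000134). Large falls were also called in a part of AT4G03380 without exons (350.4 ± 254.5 to 1.39 RPM), beside the pseudogene AT2G03860 (256 ± 116 to 1.27 RPM), beside AT1G61920 (143 ± 39.8 to 0.389 RPM) and at the endoglucanase gene GH9B12 (100.1 ± 22.3 to 0.126 RPM). The largest rises were on chromosome 2 at 9313001 to 9314000, 1204 bp from AT2G21850 (1.23 ± 0.395 to 53.5 RPM; log2 fold change 4.62, SE 0.40, limma adjusted p = 0.000182), and on chromosome 3 at 10741001 to 10742000, 71 bp from AT3G28660 (1.66 ± 2.59 to 30.9 RPM). Windows near AT3G42140 (12.0 ± 4.21 to 194 RPM), over AT5G28615 and AT5G28620 (4.16 ± 1.95 to 65.6 RPM) and over the pseudogene AT4G07522 (6.82 ± 1.56 to 97.6 RPM) followed.

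Pericentromeric windows made up 68.2% of all tested windows, 33.1% of those that fell in aly1-2 and 80.4% of those that rose. Windows over pseudogenes made up 41.6% of tested windows, 5.80% of those that fell and 66.6% of those that rose, and windows over protein-coding genes 22.2%, 45.2% and 13.1%. Windows over neither a protein-coding gene nor a pseudogene, which can hold non-coding genes, made up 37.9% of tested windows, 50.6% of those that fell and 22.0% of those that rose. Each of these shares differed from that of the other tested windows in Fisher's exact test (two-sided, largest Benjamini-Hochberg adjusted p = 3.20e-29 in a family of 32 tests), although neighbouring windows are not independent replicates. The median wild-type level was 14.5 RPM in windows that fell and 4.91 RPM in those that rose. On the log2(RPM + 1) scale a low window can fall only a little. These shares therefore compare windows of unlike level as well as unlike place. The count of windows that rose depended on scaling and on wild-type libraries: it was 652 of 5354 called under TMM, 25 of 748 under scaling to equal miRNA sums and 166 of 2323 in DESeq2, and without wild type 1, 2 or 3 it was 1098, 505 or 6627. The count that fell was 2892 to 4120 without 1 wild-type library, 4702 under TMM and 723 under miRNA scaling; the median log2 fold change of all windows was 0.51, 0.07 under TMM and 0.82 under miRNA scaling.

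In pol V, 24-nt small RNAs fell at 4228 windows and rose at 378. The window at 18873001 to 18874000 on chromosome 3, over the calmodulin-like gene CML41, fell from 249 ± 22.1 to 0.169 RPM (log2 fold change -7.74, SE 0.38, limma adjusted p = 9.51e-05), and was at 13.3 RPM in aly1-2. A window over the transporter gene UMAMIT8 on chromosome 4, at 9357001 to 9358000, fell from 258 ± 214 to 0.165 RPM, and the windows at AT3G28420, AT2G03860 and AT1G61920 that fell in aly1-2 fell in pol V to 0.282, 0.423 and 0.0940 RPM. The largest rise was at 11479001 to 11480000 on chromosome 3, in the protein-coding gene AT3G29639 (8.32 ± 1.64 to 123 RPM; log2 fold change 3.75, SE 0.40, limma adjusted p = 0.000306). Windows near AT5G33405, AT1G60095, AT1G43210 and AT3G06295 rose to 120.0, 170.1, 28.4 and 32.6 RPM from wild-type means of 8.41, 13.8, 1.70 and 2.44 RPM. Of the windows that fell, 34.3% were pericentromeric, 42.0% overlapped a protein-coding gene, 6.48% a pseudogene and 53.1% neither; of those that rose, 88.4% were pericentromeric, and 45.2% overlapped a pseudogene, a share that did not differ from that of the other tested windows (Fisher's exact test, adjusted p = 0.185). The median wild-type level was 13.7 RPM in windows that fell and 6.64 RPM in those that rose, so these shares too compare windows of unlike level. Without wild type 2 or 3, 190 or 1719 windows rose. Under scaling to equal miRNA sums 0 windows rose and 2074 fell in limma (median -0.61 against 0.11), with 4217 at an unadjusted p under 0.05. Under TMM in limma 637 rose and 4669 fell. edgeR, also scaled by TMM, and DESeq2, scaled by its own size factors, called 1364 and 166 higher.

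In dcl2 few 24-nt windows differed from wild type: 12 fell and 4 rose. The window at 24082001 to 24083000 on chromosome 1, over ILA and AT1G64795, was at 69.0 ± 19.6 RPM in wild type and at 0 in dcl2. The window at 2656001 to 2657000 on chromosome 5, 54 bp from the carboxypeptidase-like gene scpl35, fell from 90.6 ± 30.8 to 0.377 RPM (log2 fold change -5.99, SE 0.48, limma adjusted p = 0.00452). Windows over AT1G30670, over the genes AT5G04435 and AT5G27730 and over AMSH1 were at 19.5 ± 3.16, 17.6 ± 8.15 and 15.3 ± 0.788 RPM in wild type and at 0 in dcl2. Windows near the pseudogene AT1G34250 and near the cytochrome P450 gene CYP78A9 were at 32.1 and 21.5 RPM in dcl2 and at 0 in all 3 wild-type libraries, and windows over AT4G09500 and AT4G22430 rose to 60.9 and 17.7 RPM. The last 2 calls ended without wild type 2. Without wild type 1, 13 windows were higher and 34 lower, but without wild type 3 the balance turned to 237 higher and 74 lower, and without a filter to 79 and 37. Under miRNA scaling 8 rose and 9 fell, and the median of all windows was 0.42 against 0.16, and 0.00 under TMM.

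The 24-nt windows that fell in aly1-2 were largely those that fell in pol V. Both mutants lost 3264 windows in common, 92.8% of those of aly1-2 and 77.2% of those of pol V. They shared 320 risen windows, 84.7% of those of pol V but only 14.7% of those of aly1-2. Independent lists of these sizes would share 639.9 and 35.3 windows. Simulated unchanged libraries set against the same 3 wild-type libraries shared 0 and 0.2. Such libraries give so few calls that a value near 0 was fixed in advance, so it does not weigh on the overlap. All 12 windows that fell in dcl2 also fell in aly1-2, and 11 of them fell in pol V, where independent lists would share 1.82 and 2.18. Simulated unchanged libraries shared 0.1 and 0.1, again with few calls to share. Across windows, which are not independent replicates, the log2 fold changes of aly1-2 and pol V had r = 0.926 and a covariance of 1.70, against 0.249 and 0.0482 for the simulated libraries, a difference in covariance of 1.65. With a different wild-type library as the control of each mutant, r was 0.832 to 0.876 over 6 pairs of controls, and 0.00221 to 0.185 for aly1-2 and dcl2.

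**Figure D2:**
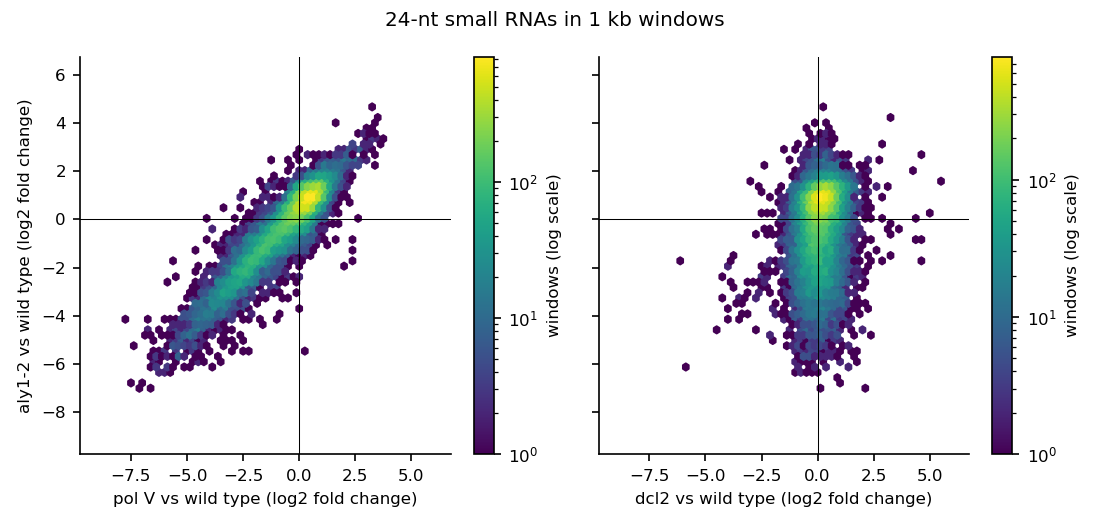
Log2 fold change of 24-nt small RNAs against wild type in 23243 windows of 1 kb, aly1-2 on the y axis and pol V (left) or dcl2 (right) on the x axis; colour is the number of windows on a log scale. Windows lie along the diagonal for pol V (r = 0.926) and not for dcl2 (r = 0.181), and each mutant is 1 library set against the same 3 wild-type libraries.

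Set directly against each other, aly1-2 and pol V differed at 0 windows in limma, with 1408 windows at an unadjusted p under 0.05; edgeR called 0 and DESeq2 21 of the 8823 to which it gave an adjusted p, and 33 or 28 were called without wild type 1 or 3. The comparison rests on 1 library per side, and a missing call does not show equal levels: the window at CML41, for example, was at 13.3 RPM in aly1-2 and 0.169 RPM in pol V. The median log2 difference over all windows was 0.38, 1.38 under miRNA scaling and 0.01 under TMM. Against pol IV, 20521 windows were higher and 78 lower in aly1-2. The window at 10570001 to 10571000 on chromosome 2, 54 bp from AT2G24800, stood at 693 RPM in aly1-2 and 0.396 RPM in pol IV, and the windows of MIR319a, MIR319b, MIR160c and AT4G26255 were the lowest in aly1-2 relative to pol IV. TMM gave 14344 higher and 2156 lower there (median 1.51 against 2.94). Under miRNA scaling 18755 were higher and 1, the MIR319a window, lower (median 3.87). The balance turned in edgeR, with 2 higher and 295 lower, and in DESeq2, with 330 higher and 372 lower among 4317 windows given an adjusted p. The edgeR fit was scaled by TMM, with factors of 0.0451 in pol IV and 2.19 in aly1-2. DESeq2 used its own size factors, so neither balance is a check apart from scaling. Against dcl2, 518 windows were higher and 2635 lower in aly1-2. The window in AT4G03380 stood at 1.39 RPM in aly1-2 and 1244 RPM in dcl2 (log2 difference -9.03, SE 0.79, limma adjusted p = 0.000657), and a window over AT2G27229 at 24.2 RPM in aly1-2 and 0.0444 RPM in dcl2. Without wild type 3, 5739 windows were called in this contrast, and miRNA scaling left 8 higher and 485 lower.

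Windows that depended on Pol IV, those that fell in pol IV with a log2 fold change of at most -2, numbered 17847. Of these, 3459 fell in aly1-2 (19.4%), 4172 in pol V (23.4%) and 12 in dcl2 (0.0672%), and 1506 (8.44%), 266 (1.49%) and 0 rose. At the rates of all tested windows, a set of this size would hold 2701, 3246 and 9.21 fallen windows. It would hold 1669, 290 and 3.07 risen ones. On the log2(RPM + 1) scale a fold change of at most -2 leaves out the windows of lowest wild-type level, where a fall can hardly be called. A threshold of -3 leaves out more of them. More falls and fewer rises than these numbers can therefore follow from level alone, and the comparison cannot separate level from dependence on Pol IV. Unchanged libraries simulated against the same wild-type libraries gave 0.00509%, 0.00539% and 0.00449% fallen. They were drawn from the same spread that the test assumes, so a rate near 0 was fixed in advance. It does not cover false calls from batch or composition of a single library. The median log2 fold change of the dependent windows was -3.07 in pol IV, 0.31 in aly1-2, -0.06 in pol V and 0.14 in dcl2, while the medians of the wild-type libraries about their own mean had an SD of 0.18 (n = 3). The aly1-2 median was 0.73 under miRNA scaling and -0.07 in the 9429 windows with a fold change of at most -3, so its sign rested on the threshold, and the pol V median was -0.70 under miRNA scaling. Risen windows in aly1-2 were 723, 350 or 4014 without wild type 1, 2 or 3, with the dependent set drawn again each time.

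Along the chromosomes, 24-nt reads of aly1-2 and pol V had a higher ratio of pericentromere to arm than those of wild type. Pericentromeres are the gene-poor regions beside the centromeres. As shares of the library, 34.4% lay in pericentromeres and 21.4% in arms in aly1-2, and 27.7% and 20.3% in pol V. The wild-type ranges were 24.6 to 30.8% and 21.8 to 28.1%. Pol V thus left the range in the arms alone, and dcl2, at 32.2% and 28.4%, lay above both ranges. The ratio of pericentromeric to arm 24-nt reads was 1.61 in aly1-2, 1.36 in pol V, 1.13 in dcl2 and 0.518 in pol IV, against 1.09 ± 0.0425 in wild type. The pol IV ratio rested largely on few bins of 1 Mb. The bin from 14 Mb on chromosome 3, in the pericentromere, held 6966 RPM. The bin from 0 Mb on chromosome 2, in the arm, held 6122 RPM. The aly1-2 ratio was 12.2 wild-type SDs above the wild-type mean, and was 6.77 to 10.4 SDs above it on each of the 5 chromosomes. In pol V the ratio was above the wild-type range on each chromosome, from 1.06 SDs above the mean on chromosome 4 to 7.52 on chromosome 1. 24-nt reads in pseudogenes were 11.6% of the library in aly1-2, 8.79% in pol V, 8.21% in dcl2 and 0.0762% in pol IV, against 6.83% ± 0.901. 24-nt reads in unannotated nuclear sequence were 33.3%, 29.2%, 40.03% and 0.884% in the same order, against 33.9% ± 4.77, and those in protein-coding genes 7.91%, 7.24%, 8.86% and 0.864%, against 7.35% ± 1.06. No test was run on these ratios and shares. With libraries scaled to equal miRNA sums the pseudogene log2 ratio of pol V turned from 0.36 to -0.64.

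**Figure D3:**
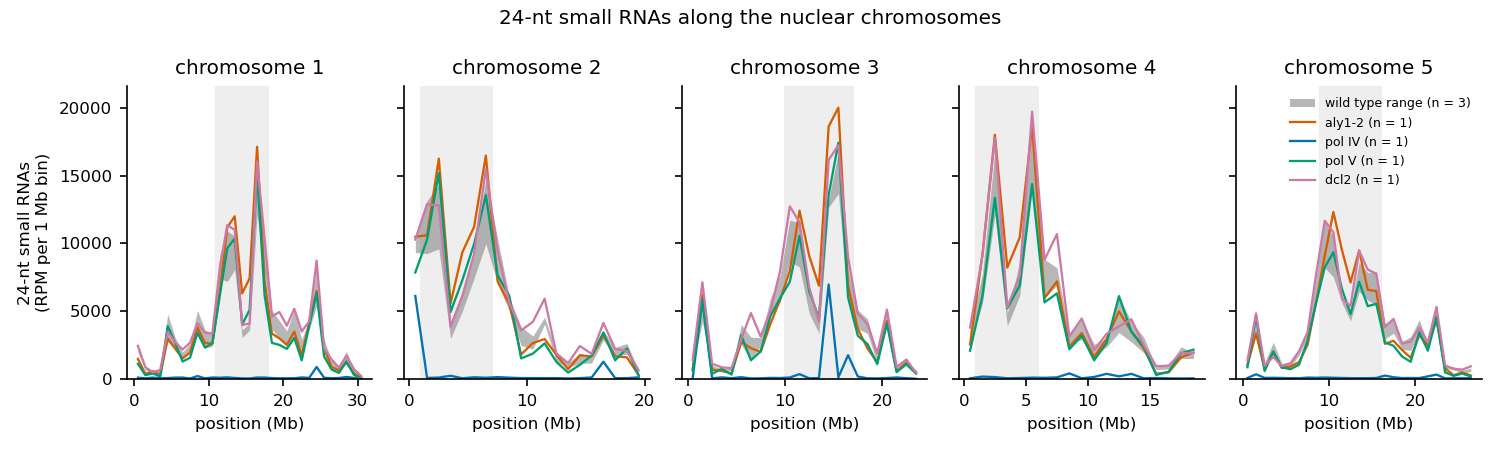
24-nt small RNAs (y axis, RPM per 1 Mb bin) along the 5 nuclear chromosomes (x axis, Mb). The grey band is the range of the 3 wild-type libraries, each coloured line a single mutant library and the light shading the pericentromeric interval used. Pol IV lies near 0 outside a few bins, and aly1-2 exceeds the wild-type range in many pericentromeric bins but not in all (ratio to arms 1.61 against 1.09 ± 0.0425).

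miR166 and miR165 stood above all 3 wild-type libraries in pol IV and pol V, but no miRNA or tasiRNA passed the test in any mutant. miR166, which targets class III homeodomain leucine zipper genes of leaf and meristem patterning, was at 449306 RPM in pol IV, 189634 in pol V and 110557 ± 64372 in wild type. miR396b, which targets growth-regulating factor genes, was at 9001 RPM in pol IV, 4906 in pol V, 3513 in aly1-2 and 256 in dcl2, against 1319.9 ± 573. Of 43 sequences tested, 34 lay above all 3 wild-type libraries in pol IV and 0 below. The numbers were 16 and 3 in aly1-2, 13 and 2 in pol V, and 10 and 15 in dcl2. Chance gives 25% on each side for a single sequence, but the 43 share each library's scaling and are not separate draws. In pol IV the 24-nt class was 3.56% of reads against 51.2% in wild type, which by itself raises the RPM of other classes. limma called 0 in each mutant, with 0, 3, 0 and 1 at an unadjusted p under 0.05 in aly1-2, pol IV, pol V and dcl2 and smallest adjusted p of 0.901, 0.295, 0.997 and 0.637. edgeR called 0 in each, and DESeq2 called 1, lower in pol V, and 0 in the others. Median log2 fold changes were 0.72, 1.65, 0.22 and -0.11, and 1.04, -0.43, -0.59 and 0.18 when listed miRNAs were scaled to equal sums. Under that scaling 9 of the 21 miRNAs and tasiRNAs examined by name in pol IV and 8 of 19 in pol V changed sign. It shifts every value of a library by a factor set mostly by miR166 and miR165, so these sign changes follow from that shift. In simulated data 0 of 12 changed miRNAs were recovered, so the spread of the wild-type libraries limited this test.

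The miRNAs that control the silencing machinery were miR162, miR168, miR403 and miR823, which target DCL1, AGO1, AGO2 and CMT3. miR823 stood at 22.7 RPM in aly1-2 and 4.86 ± 4.57 in wild type, and miR403 at 2750.4 RPM in aly1-2, 5321 in pol IV and 2116 in pol V against 1391 ± 230.4. miR168 was at 1096 RPM in aly1-2 and 2840.3 in pol IV against 605 ± 427, and miR162 at 3291 RPM in pol IV and, within the wild-type range of 84.5 to 1082 RPM, at 86.0 in dcl2. Among the tasiRNAs, tasiR-ARF(D7), which targets auxin response factor genes, was at 26.9 RPM in aly1-2, 12.8 in dcl2 and 223 in pol IV against 62.3 ± 25.3, and TAS1-siR255 at 23.9, 10.2 and 43.1 RPM against 8.85 ± 0.830. Members of the phasing trigger list, which start secondary siRNA production, included miR390 (188 RPM in dcl2 and 2438 in pol IV, against 708 ± 557) and miR472 (5.55 in aly1-2 and 79.5 in pol IV, against 12.9 ± 5.92). The development list had 14 of 17 members above all wild-type libraries and 0 below in pol IV, 6 and 0 in aly1-2, 7 and 1 in pol V, and 4 and 7 in dcl2. The auxin list had 1 of 2 above in pol IV and 0 on either side in the other mutants. Of the 5 other miRNAs, 4 lay above in pol IV, 3 in aly1-2, 1 in pol V and 2 in dcl2, where 2 lay below, among them miR822 at 17.7 RPM in aly1-2 and, below, at 1.51 RPM in dcl2 against 10.2 ± 4.13. In every list and mutant, the number called was 0 over all features tested and 0 adjusted over the list alone, with a smallest adjusted p over a list alone of 0.110 for the tasiRNA list in pol IV.

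Markers of older flowers and of nutrient state were among the lists. miR845a, known from pollen, was at 14.1 RPM in aly1-2, below all 3 wild-type libraries, and at 34.7 RPM in pol V and 45.1 RPM in pol IV, above them, against 24.6 ± 5.35. Of the nutrient list, the copper-responsive miR397a was at 64.9 RPM in dcl2 and 0, 0 and 34.2 RPM in the wild-type libraries, and miR408 at 343 RPM in pol IV and 160.0 in dcl2 against 59.4 ± 66.5. miR398b,c, also copper-responsive, ranged from 2.26 to 1125 RPM over the 3 wild-type libraries.

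**Figure D4:**
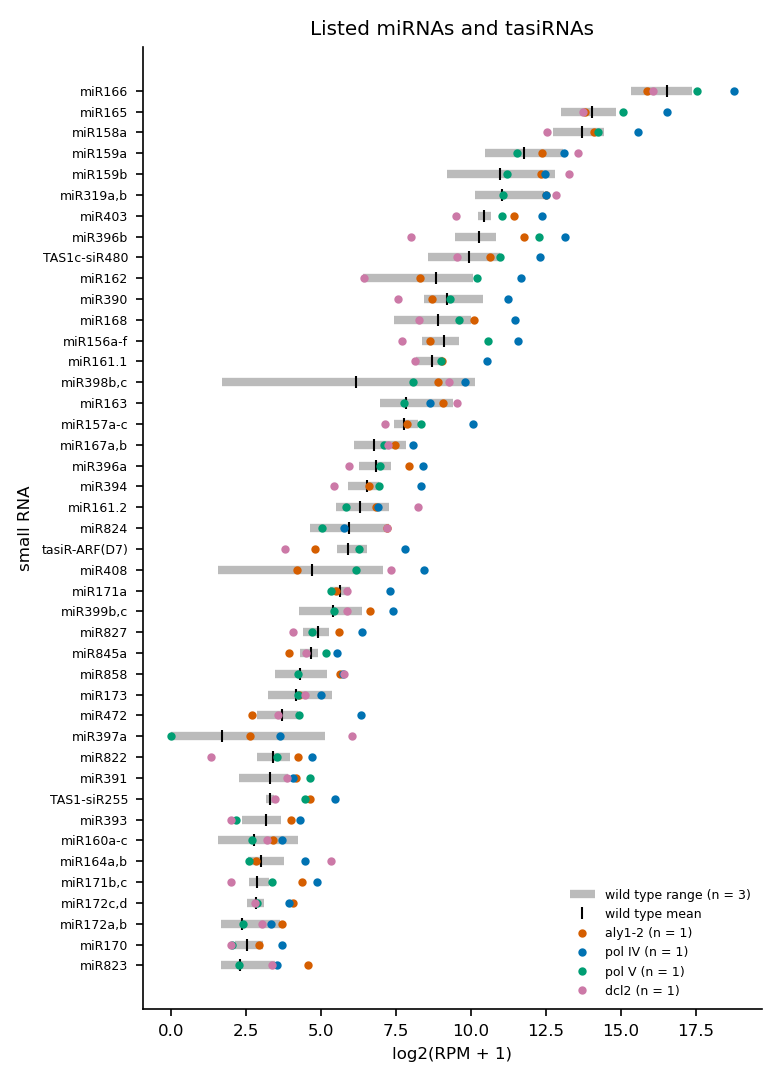
Level of the 43 tested miRNAs and tasiRNAs (rows) as log2(RPM + 1) on the x axis. Grey bars span the 3 wild-type libraries, ticks are their mean on the log scale and coloured points are single mutant libraries; 34 points of pol IV lie above the wild-type range, and 9 of the 21 examined by name in pol IV change sign when listed miRNAs are scaled to equal sums.

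Summed 21-nt and 22-nt small RNAs of genes fell most widely in pol IV, where 1204 of 1285 pseudogenes fell. Of 2681 genes tested, 1898 fell and 313 rose in pol IV. The lncRNA gene AT3G08370 (chromosome 3, 20030910 to 20031192) was at 157 ± 25.3 RPM in wild type and at 0 in pol IV, and the protein-coding gene AT3G18700 (chromosome 3, 6431722 to 6432905) fell from 272 ± 95.9 to 0.791 RPM (log2 fold change -7.19, SE 0.50, limma adjusted p = 8.15e-05). AT3G21170, AT1G49260 and AT4G08545 fell to 0.396, 0.396 and 5.54 RPM. AT2G02750 (chromosome 2, 771151 to 773552) rose from 31.1 ± 18.3 to 392 RPM and the misc_RNA gene AT3G00580 from 0.0915 ± 0.158 to 14.6 RPM, followed by AT5G00540, AT4G02885 and AT3G05955 at 25.6, 36.6 and 14.6 RPM; snRNA genes rose in 26 of 33 cases. Under miRNA scaling 1 gene rose and 1561 fell, and the median over genes was -2.62 against -1.96.

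The TAS genes, which make tasiRNAs, and the transcripts known to make phased siRNAs gave more 21-nt and 22-nt small RNAs in pol IV, in RPM, where all 5 tested TAS genes, all 13 tested phased transcripts and 3 of 4 silencing factors rose. The DNA glycosylase gene ROS1 was at 0 against 3.28 ± 1.02 RPM and was called lower. The direction of the rises depended on scaling: with libraries scaled to equal miRNA sums no rise remained called, and 4 of the TAS genes, all 13 phased transcripts and AGO2 had negative log2 fold changes, while TAS1C, AGO1 and DCL1 stood at 0.01, 0.19 and 0.03. TAS2 (chromosome 2, 16539384 to 16540417) was at 2502 RPM in pol IV, 1732 in aly1-2, 1306 in pol V and 583 in dcl2 against 738 ± 62.6, and TAS3 (chromosome 3, 5861491 to 5862437) at 2335 RPM in pol IV and 256 in dcl2 against 600.4 ± 183. The auxin receptor gene AFB3 was at 44.3 RPM in pol IV against 12.7 ± 2.12, and AT1G63150, of a cluster of pentatricopeptide repeat genes on chromosome 1, at 208 RPM against 62.4 ± 6.07. AGO1 was at 62.9 RPM and DCL1 at 31.6 RPM in pol IV, against 12.7 ± 1.35 and 7.396 ± 2.07. Adjusted over the list alone, 5 TAS genes, 13 phased transcripts and 4 silencing factors were called in pol IV, the numbers called over all genes tested. TAS1B, TIR1 and AGO2 lost their calls without wild type 2, and AT1G62670 and AT1G62860 without wild type 1. In aly1-2, pol V and dcl2 limma called 0 members of these lists over all genes tested and 0 adjusted over the list alone, with smallest adjusted p over a list alone of 0.0789, 0.329 and 0.172. TAS2 was called higher in aly1-2 when low values were not filtered (log2 fold change 1.23). TAS3 was called lower in dcl2 when 22-nt small RNAs were tested alone (log2 fold change -1.36), and AGO2 without wild type 3 (-1.65).

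In aly1-2, 17 genes gained and 30 lost 21-nt and 22-nt small RNAs, and in pol V 10 gained and 31 lost them. The lncRNA gene AT1G07233 (chromosome 1, 16645544 to 16646093) fell from 20.97 ± 8.01 RPM to 0.0421 in aly1-2 and 0.141 in pol V (log2 fold changes -4.34 and -4.21, SE 0.49, limma adjusted p = 0.0326 for each). AHG1, a protein phosphatase gene of abscisic acid signalling (chromosome 5, 21026805 to 21029188), was at 15.8 ± 5.42 RPM in wild type and 0 in both mutants, and AT3G27400 fell from 11.5 ± 1.90 to 0.126 and 0.141 RPM. AT1G59835 and AT2G46765 also fell in aly1-2, to 0.252 and 0.884 RPM, and AT1G49260 and AT1G13760 in pol V, to 3.10 and 1.13 RPM. AT5G28620 (chromosome 5, 10612529 to 10613004) rose from 0.141 ± 0.244 to 13.6 RPM in aly1-2, and TAT3, a tyrosine aminotransferase gene (chromosome 2, 10582074 to 10585216), from 0.563 ± 0.975 to 25.1 RPM in pol V, along with AT2G10965 (29.5 RPM) and AT3G29639 (11.4 RPM). The overlapping genes AT3G29645 and AT3G05885 rose in both mutants and AT2G14765 and AT2G14796 in aly1-2; sums over both strands cannot tell such partners apart. Without wild type 2, and with every library thinned to 2367811 reads, limma called 0 genes in either mutant (492 and 273 at an unadjusted p under 0.05 without wild type 2, and 619 and 251 after thinning). Without wild type 1 or 3 it called 120 or 369 in aly1-2 and 109 or 194 in pol V. The balance in aly1-2 turned to 227 higher and 142 lower without wild type 3, and to 154 higher and 37 lower without a filter. edgeR called 206 in aly1-2 and 105 in pol V, and DESeq2 48 and 22. Scaling to equal miRNA sums left 0 higher and 2 lower in aly1-2 and 0 higher and 4 lower in pol V (medians over genes 0.80 against 0.49 and -0.62 against 0.08), and TMM gave 14 higher and 105 lower in aly1-2 (median -0.01).

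In dcl2 the 22-nt small RNAs of genes and pseudogenes were reduced, while the sum of 21 and 22 nt gave no call. Tested alone, 22-nt small RNAs fell at 609 of 1537 genes and rose at 4. 22-nt reads in pseudogenes were 0.289% of the dcl2 library against 0.849% ± 0.117 in wild type, and those in protein-coding genes 0.439% against 1.19% ± 0.143, both below all 3 wild-type libraries. 22-nt reads of the TAS genes summed to 421 RPM in dcl2 and 663 to 771 RPM in wild type, and their 24-nt reads to 1294 RPM against 486 to 848 RPM. In aly1-2, 22-nt reads in pseudogenes were 1.40% of the library and those of TAS genes 1276 RPM, both above all 3 wild-type libraries. For the sum of 21 and 22 nt, limma called 0 of 2681 genes in dcl2, with 567 at an unadjusted p under 0.05; edgeR and DESeq2 called 0, and without wild type 1 or 3 limma called 9 or 273. The median log2 fold change over genes was -0.56, -0.40 under miRNA scaling and 0.00 under TMM.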

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

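The signal in this part lies outside the tested comparisons, and it was looked at among 16 pairs of mutated gene and mutant. Small RNAs of 18 to 28 nt matching NRPE1, the gene of the largest Pol V subunit, stood at 8.25 RPM in the pol V library (exact Poisson 95% interval 6.27 to 10.7), above the 1.61, 1.098 and 1.27 RPM of the wild-type libraries. It was flagged because it was above the level of the control samples in a gene that the test of genes left out, being under its filter on low values. Of 46 reads of 21 or 22 nt with 1 genome match in NRPE1, 23 were sense, 23 antisense and 45 on the 3-prime side of its midpoint. The intervals hold counting error alone, and no explanation was tested.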

How the results depend on the processing

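Few libraries limited the results, and totals varied with scaling and with the wild-type library left out. Thinning moved the totals of genes in aly1-2 and pol V and of windows in dcl2. A total of calls was taken as the same within 1.5 times the main total, and a value within 1 SD of wild type. By these limits, 270 alternatives left main values and counts the same and 87 moved them; for named features, 2471 left them the same, 330 moved them, 202 ended the call, 3 gained one and 18 reversed the direction. Thinning, and testing every annotated mature miRNA, were chosen after seeing the data. A pseudocount of 0.25 changed no total by more than 1.5 times, but took called genes from 17 higher and 30 lower to 10 and 59 in aly1-2, and from 10 and 31 to 4 and 56 in pol V. No paired analysis was possible because only wild type has replicate numbers. Scaling to equal miRNA sums cannot move the ratio of pericentromere to arm, and at 500 bp a named window stands for the part that starts at the same coordinate, with no value where that part was under the filter. Tests without a filter, after thinning, with 1 match, at 500 bp (27246 windows), with 21 or 22 nt alone, of other miRNA sequences and in DESeq2 cover other numbers of features. DESeq2 gave an adjusted p to 2514 windows in pol IV, 4317 between aly1-2 and pol IV, 8823 between aly1-2 and pol V and 17835 between aly1-2 and dcl2, of 23243. The cause of the changes was not tested.

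Under miRNA scaling the pol IV log2 fold changes of listed genes turned negative: TAS1A -0.47, TAS1B -0.79, TAS2 -0.34, TAS3 -0.10, AFB2 -0.19, TIR1 -0.43, AFB3 -0.27, AGO2 -0.059, AT1G62590 -0.33, AT1G62670 -0.56, AT1G62860 -0.50, AT1G62910 -0.27, AT1G62930 -0.38, AT1G63080 -0.53, AT1G63130 -0.14, AT1G63150 -0.36, AT1G63330 -0.36 and AT1G63400 -0.47. The log2 ratios to wild type under this scaling were, for pol IV, -0.33 at 21 nt (from 1.73), -2.46 at 22 nt (-0.20), -6.14 at 24 nt (-3.85), and at 24 nt -8.78 in pseudogenes (-6.49), -5.39 in protein-coding genes (-3.09) and -7.56 in unannotated sequence (-5.26). For pol V they were -0.22 (0.55), -1.05 (-0.07), -1.10 (-0.09), -0.64 (0.36), -1.03 (-0.02) and -1.23 (-0.22), and for aly1-2 0.34 at 22 nt (0.18). With 1 match, pol IV had -6.78, -3.40 and -6.27 in these classes at 24 nt and a log2 ratio of pericentromere to arm of -1.43 (-1.07). That ratio was -1.17 without reads matching annotated tRNA or rRNA genes or the organelles.

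Genes called in aly1-2 (47) numbered 191 without a filter, 2 under miRNA scaling, 119 under TMM, 206 in edgeR, 0 when thinned, 82 with 1 match, 0 at 21 nt, 0 at 22 nt and 0 to 369 with each wild-type library left out. In pol IV (2211) they were 1239 without a filter, 1390 with 1 match, 933 at 21 nt and 1355 at 22 nt. In pol V (41) they were 4 under miRNA scaling, 75 under TMM, 105 in edgeR, 22 in DESeq2, 0 when thinned, 70 with 1 match, 5 at 21 nt, 5 at 22 nt and 0 to 194 with a library left out. In dcl2 (0) they were 100 without a filter, 613 at 22 nt and 0 to 273 with a library left out. DESeq2 called 1 miRNA in pol V (0).

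Windows called in aly1-2 (5691) numbered 3332 without a filter, 748 under miRNA scaling, 2323 in DESeq2, 3547 with 1 match and 3397 to 10747 with a library left out. In pol IV (22843) they were 14550 without a filter, 266 in edgeR, 645 in DESeq2 and 14776 with 1 match, and in pol V (4606) 1991 without a filter, 2074 under miRNA scaling and 2377 in DESeq2. In dcl2 (16) they were 116 without a filter, 6 in DESeq2, 9 when thinned and 14 to 311 with a library left out. Between aly1-2 and pol IV (20599) they were 297 in edgeR (2 higher), 702 in DESeq2 (330 higher) and 12389 with 1 match. Between aly1-2 and pol V (0) they were 381 without a filter, 21 in DESeq2, 1 with 1 match, 1 at 500 bp and 0 to 33 with a library left out. Between aly1-2 and dcl2 (3153) they were 493 under miRNA scaling, 5002 in edgeR, 1607 in DESeq2 and 2523 to 5739 with a library left out. The median log2 fold change of windows dependent on Pol IV was, in aly1-2 (0.31), 0.51 and -0.072 with thresholds of -1 and -3, 0.73 under miRNA scaling and 0.11 with 1 match, in pol V (-0.06) -0.36 at -3 and -0.70 under miRNA scaling, and in dcl2 (0.14) 0.41 under miRNA scaling.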

Other observations

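Plant Argonaute proteins sort small RNAs partly by their first base, and AGO4, the effector of 24-nt siRNAs, is known to favour A. A was the first base of 60.9% ± 2.36 of 24-nt reads in wild type, 61.0% in pol V, 57.5% in aly1-2, 56.7% in dcl2 and 39.2% in pol IV. G was the first base of 12.3% of 24-nt reads in aly1-2 against 10.2% ± 0.559. Of the 24-nt reads that remained in pol IV, windows of chromosome 3 at 14201001 to 14202000, over the misc_RNA gene AT3G06365, and at 1964001 to 1965000 stood at 1423 and 1377 RPM, against 302 to 703 and 463 to 962 RPM in wild type. A window of chromosome 2 at 7001 to 8000 stood at 1188 RPM in pol IV and 207 to 592 RPM in wild type. Sequences with several matches were divided equally, so copies of a repeat cannot be told apart. Only 11 genes are annotated as rRNA. Whether these reads are siRNAs or fragments of abundant RNAs such as rRNA was not examined. These windows were picked by their pol IV level after the values were seen, and none of these values was tested.

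The tests of depth, of the shared wild-type libraries, of a mix with pol V, of scaling and of the chromosome ratio in aly1-2, and of dilution and RNA quality in wild type, were chosen after the results they bear on were seen. For depth and for the shared wild-type libraries, the limits that decide were written before the test was run.

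The 24-nt windows that fell in aly1-2 were largely those that fell in pol V. Greater depth of both libraries is argued against, because 89.9% of the windows called lower in aly1-2 were also called lower in pol V with every library thinned to 2367811 reads. Chance values of the shared wild-type libraries are argued against as the whole cause, because the lowest correlation with different wild-type controls was 0.832. An aly1-2 library made from the same pol V plants, or mostly mixed with them, is argued against only if NRPE1 small RNAs of 21 and 22 nt mark those plants. Their upper 95% limit in aly1-2 was 0.912 RPM, 13.8% of the pol V point value of 6.63 RPM. The error of that point value (interval 4.87 to 8.81) is left out of the 13.8%. The marker rests on 1 pol V library and was itself not tested. Material of another pol V allele and a batch shared by both libraries stay open, since the labels give no batch and no allele, and an effect of aly1-2 on the steps at which Pol V acts stays open as untested.

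In aly1-2, 2173 windows were called higher. A single scaling shift common to every window is argued against as the whole cause, because 652 windows were called higher after TMM scaling, where the median log2 fold change of the 2173 went from 1.46 (SE 0.39) to 0.93 (SE 0.32) and many calls ended because it passed under 1. Scaling to equal miRNA sums ended all but 23 of these calls while the median went to 1.82, because its SE rose to 1.104. The ratio of pericentromeric to arm 24-nt reads was 12.2 wild-type SDs above the wild-type mean, but a rise in the pericentromeres and a loss in the arms cannot be told apart by it, since 33.1% of fallen windows were pericentromeric against 68.2% of tested ones. Batch was not tested, and an effect of the genotype stays open as untested.

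The 3 wild-type libraries differed in miRNAs, and miR398b,c stood at 2.26, 101.6 and 1125 RPM. Dilution by the abundant miR165 and miR166 is argued against, because their share of 5.03 to 19.9% can put a factor of at most 1.19 between libraries. The ratio of highest to lowest was above it for all 41 other tested miRNAs and tasiRNAs (median 3.38). These include miR397a, which was at 0 in wild type 1 and 2 and so has no finite ratio. In wild type 3, the library lowest in miR166, the share of annotated tRNA, annotated rRNA and organelle reads was 1.16%, the lowest of the 3. This argues against degraded RNA in wild type 3 only in as far as such reads show it. Any rRNA reads outside the 11 genes annotated as rRNA are not counted. Over the tested miRNAs and tasiRNAs, wild type 3 had a Spearman correlation of 0.964 with dcl2, 0.901 with wild type 2 and 0.781 with wild type 1. By deposited sample number, wild type 3 stands with aly1-2, dcl2 and pol V, and wild type 1 and 2 stand with pol IV. A difference between these sets may be part of the wild-type spread, and it was not tested. Plants, growth and batch are not given by the labels, and no biological explanation was tested.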
